A study of Mus musculus with 23 samples.

How the data were processed

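Gene expression was measured on Affymetrix Mouse Gene 1.0 ST arrays in ear pinna tissue of 4-week-old mice, per the labels. The 23 arrays came from 12 Rhbdf2+/+ mice of the C57BL/6J strain, called wild type here, and 11 Rhbdf2cub/cub mice, called cub. Each array was labelled as a separate biological replicate. A 2-mm hole was punched through the ear, and a 3-mm biopsy punch then took the 1-mm rim around it, so that each wounded sample was a ring of wound edge. Tissue was taken 15 min, 2 h and 24 h after wounding, and from unwounded ears at 0 h. No hole or biopsy size was recorded here for the 0 h samples. Wounded and 0 h samples may therefore also differ in the piece of tissue taken. Each of the 8 groups had 3 arrays except cub at 15 min, which had 2.

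The authors deposited log2 values that were background corrected, quantile normalized and summarized by RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes for the software and the method. The summarization level, the annotation release and the genome build of the array were not given in the sources used here. The table held 35556 rows with values to 2 decimals, from 2.92 to 13.84, and array medians from 6.37 to 6.46. The number of arrays limits the precision of every value.

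Of the rows, 21789 carried 1 gene symbol, 1621 carried several and 12146 were not named. The 1621 rows with several symbols and the unnamed rows were left out of the gene tests. Gene IDs of 21698 named rows matched the reference gene table of the GRCm38.p6 assembly, which served only for names and for the order of neighbouring genes. For the 999 genes with more than 1 row, the row with the highest mean was used, which left 19938 genes.

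Values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, 15 residual degrees of freedom and empirical Bayes moderation, which added 5.61 prior degrees of freedom. Fits used all 23 arrays. There were 14 comparisons: cub against wild type at each time and averaged over the 4 times, each wounded time against 0 h within each genotype, and the difference of the wounding change between the genotypes at each wounded time, called an interaction. P values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The authors' own test, R/maanova with q values, was not run here. Log2 differences are given with their standard error and group levels with the standard deviation, and all gene tests were two-sided.

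For each comparison, the named genes were the 12 with the largest positive and the 12 with the largest negative log2 difference past the threshold, without overlap between the groups except for interactions and the average over all times. For each gene list they were the 4 members with the largest differences past the threshold. Of these, the text mostly names genes whose call held in every alternative tried, a narrowing made after the values were seen. Another 9 genes were to be reported whatever their values, of which 8 were tested; 1 of the 9 genes was not analysed here.

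The 23 gene lists were written from general knowledge and covered NRF2 targets; EGFR ligands, receptors and sheddases; MAPK feedback targets; immediate early genes; inflammatory cytokines and chemokines; neutrophil, macrophage, T cell and mast cell markers; wound-edge keratinocyte genes; epidermal differentiation genes; hair follicle keratins and regulators; sebaceous gland, skeletal muscle, cartilage, adipocyte, fibroblast and matrix, and erythroid genes; cell division, hypoxia and glycolysis, interferon-stimulated, circadian clock and heat shock genes. Of 518 listed genes, 475 were tested, 4 of them through a synonym, and 43 were not analysed here. Lists were tested with camera in limma, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with a correlation estimated from the data. The estimated correlation was used for the main fit only, and the other alternatives kept the preset one. Camera p values were adjusted over the 23 lists of a comparison. Member counts are given over all genes tested and adjusted over the list alone. The design, the lists, the naming rule and all alternatives but 1 were chosen before the data were examined.

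The alternatives were median-centring of each array, quantile normalization over the tested genes, a filter that kept the 13741 genes with a highest group mean of at least 6, a test of every row, a fit of only the arrays of the groups compared, the replicate number as a block, no empirical Bayes moderation, moderation with trend and robust estimation, array weights, q values scaled by the share of true nulls, each array left out in turn, and windows of 25 and 100 genes around Rhbdf2 in place of 50. An average over all times without the 15 min arrays was added after the data were seen.

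The code was tested on simulated data with 200 genes of 19938 changed. The simulated values varied independently between genes, without effects shared by the genes of an array. The rates below therefore check the code and need not hold for the real arrays. For the genotype comparison at 2 h, it recovered 88.1% of genes changed by a log2 of 0.5 and 100% of those changed by 1 or 2, with 5.88% of calls false. For the smaller groups at 15 min, it recovered 77.6%, 97.0% and 100%, and for the interaction at 2 h 67.2%, 98.5% and 100%. No pair of arrays of a group was a duplicate, since at most 4.57% of values were identical in any of 22 pairs. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.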

Results

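Ear tissue of wild-type and cub mice was profiled before and after a hole was punched through the ear. Rhbdf2 encodes iRhom2, an inactive rhomboid protein that governs the maturation of the protease ADAM17, which sheds EGFR ligands and other membrane proteins. The cub allele lacks part of the gene, and mice homozygous for it close ear holes faster than wild type, so the study asked how the genotypes differ at each time after the punch. There were 3 arrays in each group at 0 h, 2 h and 24 h and in wild type at 15 min, and 2 arrays in cub at 15 min. All values are log2 RMA values, and differences between genotypes are cub minus wild type.

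The position of the Rhbdf2 probes relative to the cub mutation was not examined, so its level is only a weak check of the genotype labels. At 0 h Rhbdf2 was higher in cub, at 9.11 ± 0.04 against 8.70 ± 0.06 in wild type (SD, n = 3 each), a difference of 0.41 ± 0.09 (adjusted p = 0.00883). At 15 min it was at 9.12 ± 0.11 in cub (n = 2) and 8.78 ± 0.06 in wild type, a difference that did not pass (adjusted p = 0.0574). At 2 h the groups were level at 9.0 ± 0.12 and 9.0 ± 0.04. At 24 h Rhbdf2 was lower in cub, at 8.32 ± 0.13 against 8.81 ± 0.22 (adjusted p = 0.00218). The 24 h call ended when only the 6 arrays compared were fitted (adjusted p = 0.0729, with a range of 0.000178 to 0.0729 over the alternatives). Wounding changed Rhbdf2 in cub by −0.79 ± 0.09 at 24 h (adjusted p = 1.3e-07) and in wild type by 0.11 ± 0.09 (adjusted p = 0.345), and this difference between the genotypes passed its own test (−0.90 ± 0.12, adjusted p = 0.000676).

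Unwounded cub ears differed from wild type in single genes. Pdk4, a kinase that restrains the entry of pyruvate into mitochondria, was higher in cub, at 10.05 ± 0.54 against 7.36 ± 0.06 (SD, n = 3 each), a difference of 2.70 ± 0.22 (adjusted p = 4.19e-07). Scd3, a desaturase of sebaceous glands, was higher by 2.48 ± 0.36 (adjusted p = 0.000348), and Awat2, which makes wax esters of sebum, by 1.39 ± 0.21 (adjusted p = 0.000709). The 18 sebaceous gland genes as a list did not pass (median −0.07, mean 0.08, camera direction down, adjusted p = 0.168), with 2 higher and 4 lower, or 2 and 5 adjusted over the list alone. Krt77, a keratin of the upper epidermis and sweat ducts, was higher by 1.87 ± 0.20 (adjusted p = 1.27e-05), and the interleukin 12 receptor chain Il12rb2 by 1.36 ± 0.14 (adjusted p = 1.27e-05). Krt24, a keratin of differentiating keratinocytes, was lower, at 10.51 ± 0.14 against 11.91 ± 0.08, a difference of −1.40 ± 0.11 (adjusted p = 1.49e-07). The alcohol dehydrogenase Adh6b was lower by the same test (−1.60 ± 0.12, adjusted p = 1.49e-07), although its second probe set differed by only −0.23. Lypd6, a modulator of Wnt signalling, was lower as well (−1.32 ± 0.15, adjusted p = 2.18e-05).

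Of 23 lists, 11 stood above other genes in unwounded cub ears by camera and 0 below, and 0 of these calls held with an estimated correlation. Among EGFR ligands, receptors and sheddases, the ligand genes Btc and Epgn were higher, by 1.31 ± 0.19 (adjusted p = 0.000335) and 1.00 ± 0.16 (adjusted p = 0.00129). Of 25 epidermal differentiation genes, 11 were higher and 1 was lower, among them Krt1, the main keratin of suprabasal cells, at 1.14 ± 0.12 (adjusted p = 1.27e-05), and the cornified envelope gene Ivl at 0.70 ± 0.09 (adjusted p = 0.000205). Adjusted over the list alone, 19 were higher and 1 was lower. The list as a whole stood above all other genes by camera (median 0.27, adjusted p = 1.27e-13), but not past the threshold with an estimated correlation (adjusted p = 0.334). The EGFR list behaved alike (median 0.12, adjusted p = 0.000124; adjusted p = 0.334 with an estimated correlation), with 2 of 14 genes higher and 5 adjusted over the list alone. So did 16 macrophage markers (median 0.325, 3 higher, 7 adjusted over the list alone, adjusted p = 1.54e-05, medians of 0.153 to 0.487 over the alternatives; adjusted p = 0.551 with an estimated correlation). A camera call without support from the estimated correlation was also found for 29 skeletal muscle genes (median 0.18, 3 higher, also over the list alone, adjusted p = 3.79e-06, medians of 0.11 to 0.255; adjusted p = 0.551 with an estimated correlation). The same held for 21 fibroblast and matrix genes (median 0.15, 4 higher, 6 adjusted over the list alone, adjusted p = 5.72e-06, medians of 0.137 to 0.19; adjusted p = 0.536 with an estimated correlation). Of 12 mast cell markers 1 was higher, also over the list alone (median 0.23, adjusted p = 0.00446; adjusted p = 0.551 with an estimated correlation). This list call ended without cub 0 h replicate 2 (median 0.11, adjusted p = 0.148, range over the other alternatives 0.000615 to 0.148). Mmp3, a matrix metalloproteinase of wounds, was lower before wounding (−1.0 ± 0.12, adjusted p = 6.82e-05).

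In all, 1047 genes differed at 0 h, 663 higher and 384 lower in cub, of which 31 differed at least 2-fold. The split was 787 higher and 682 lower after quantile normalization, and 708 and 454 after median-centring. The count depended on single arrays: it was 392 and 576 without wild-type replicates 2 and 3, and 322 without cub replicate 2, which stood apart in the hair keratin Krt25 and in adipocyte genes.

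**Figure D1:**
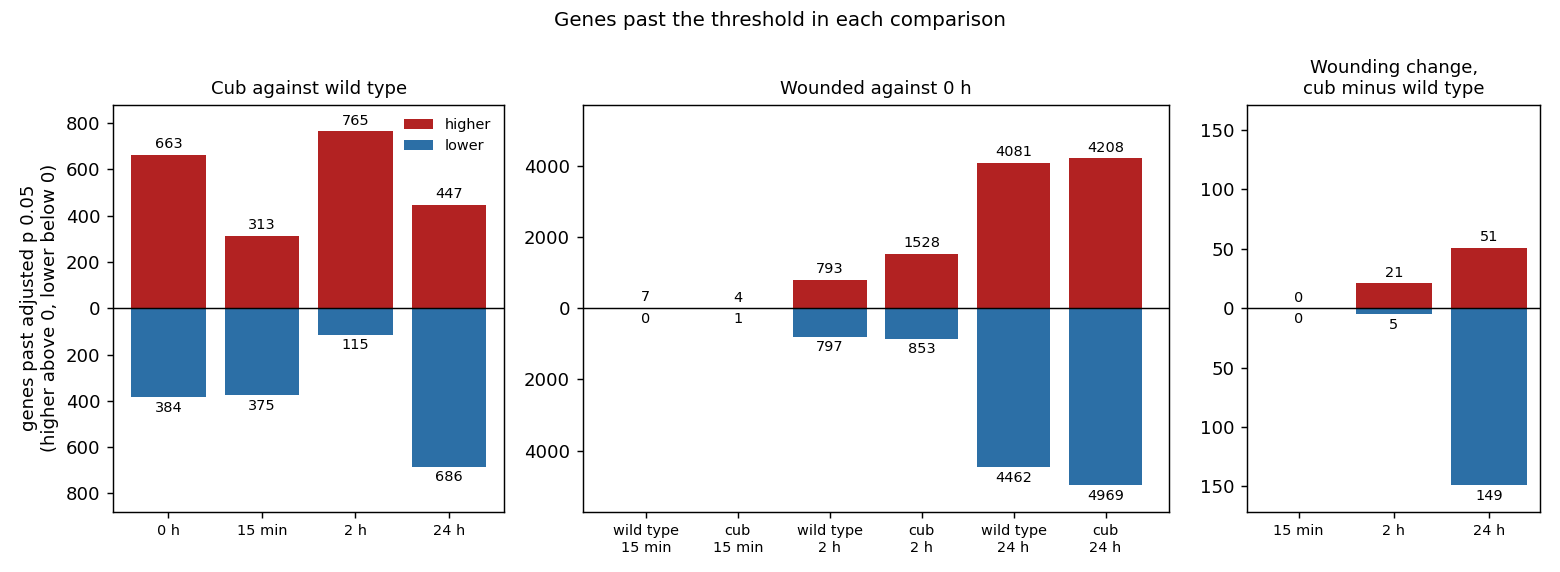
Numbers of genes past the adjusted threshold in limma (y axis, higher above 0 and lower below 0) for each comparison (x axis), with genotype comparisons, wounding comparisons and interactions in separate panels. Wounding at 24 h changed 8543 genes in wild type and 9177 in cub, and the genotype comparisons gave 1047, 688, 880 and 1133 genes from 0 h to 24 h; the split at 2 h, 765 higher and 115 lower, became 524 and 269 after quantile normalization.

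At 15 min after the punch, the genotypes differed in many of the same genes as at 0 h. Scd3 was higher in cub by 2.87 ± 0.40 (adjusted p = 0.000884) and Pdk4 by 2.12 ± 0.25 (adjusted p = 0.000126). Sectm1a, a secreted protein that acts on T cells, was higher by 1.12 ± 0.10 (adjusted p = 4.34e-06), and Tchh, the trichohyalin of the inner root sheath, by 1.21 ± 0.19 (adjusted p = 0.00261). Krt24 was lower (−1.39 ± 0.12, adjusted p = 1.28e-06), and so was Lypd6 (−1.27 ± 0.16, adjusted p = 0.000396). Of 33 hair follicle keratins and regulators, 10 were higher, or 14 adjusted over the list alone (median 0.24, camera adjusted p = 1.07e-07; adjusted p = 0.918 with an estimated correlation). The largest of these, Krt25 at 2.25 ± 0.39 (adjusted p = 0.00444), was no longer called without cub 15 min replicate 3 (adjusted p = 0.0531, the highest of its alternatives).

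The comparison at 15 min called 688 genes, 313 higher and 375 lower in cub. The count depended on single arrays: 29 genes were called without cub replicate 3, 24 higher and 5 lower, and 2025 without cub replicate 2, 1047 higher and 978 lower. Without wild-type replicates 1, 2 and 3 in turn, 235, 324 and 154 were called, and without replicate 2 the split turned to 166 higher and 158 lower. The genotype differences at 0 h and at 15 min, from separate arrays, had 116 higher and 131 lower genes in common and none of opposite sign, against 10.4 and 7.22 for independent lists (r = 0.534 across genes, which are not independent replicates). No other pair of times had as high an r. It ran from 0.0728, for 15 min with 2 h, to 0.453, for 0 h with 2 h. In these other pairs, 1 to 8 genes were called with opposite sign.

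At 2 h, matrix genes of the dermis were higher in cub. Mfap5, a microfibril protein, was higher by 0.91 ± 0.12 (adjusted p = 0.000124), elastin, Eln, by 0.72 ± 0.11 (adjusted p = 0.000482), and the fibrillar collagen gene Col3a1 by 0.69 ± 0.10 (adjusted p = 0.000384), at 11.19 ± 0.14 against 10.50 ± 0.12 (SD, n = 3 each). Of 21 fibroblast and matrix genes, 18 were higher and 0 lower by limma, and 20 adjusted over the list alone. The list stood above all other genes by camera (median 0.41, adjusted p = 4.29e-25), also with an estimated correlation (adjusted p = 0.0355). It also passed in 12 of 12 other alternatives, with medians of 0.305 to 0.477. These kept the preset correlation, so they do not show whether the call with an estimated one is stable. Outside the list, Ccn3, a matricellular growth regulator, was higher by 1.21 ± 0.11 (adjusted p = 6.89e-06), and Cthrc1, a collagen triple helix protein of wound fibroblasts, by 1.11 ± 0.12 (adjusted p = 2.08e-05).

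Some epidermal genes were higher in cub at 2 h as well. Sectm1a was higher by 1.25 ± 0.09 (adjusted p = 2.42e-07), Epgn by 1.13 ± 0.16 (adjusted p = 0.000389), Krt77 by 1.12 ± 0.20 (adjusted p = 0.00217) and Btc by 1.09 ± 0.19 (adjusted p = 0.00182). Krt24 was lower (−0.95 ± 0.11, adjusted p = 3.02e-05). Serpina3b, a protease inhibitor of the skin, was lower (−1.73 ± 0.33, adjusted p = 0.00329), as was Inmt, a methyltransferase of small amines (−1.27 ± 0.19, adjusted p = 0.000682). Of 25 epidermal differentiation genes, 6 were higher and 0 lower by limma, with the same count adjusted over the list alone (median 0.15, camera adjusted p = 4.36e-06; adjusted p = 0.404 with an estimated correlation). The wounding change of this list was lower in cub (median −0.14, camera adjusted p = 0.000579; adjusted p = 0.397 with an estimated correlation), with 0 members past the threshold by limma. Arc, an immediate early gene, was higher by 1.13 ± 0.15 (adjusted p = 0.000164), while no other of the 28 immediate early genes was called.

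Some markers of neutrophils, macrophages and mast cells were higher in cub at 2 h. Mmp8, the neutrophil collagenase, was higher by 1.11 ± 0.18 (adjusted p = 0.00141), and the myeloid lectin Clec4d by 0.74 ± 0.14 (adjusted p = 0.00431). Of 19 neutrophil markers, 8 were higher, or 10 adjusted over the list alone (median 0.39, camera adjusted p = 5.46e-07; adjusted p = 0.123 with an estimated correlation). Of 16 macrophage markers, 8 were higher, or 12 adjusted over the list alone (median 0.52, camera adjusted p = 1.52e-08; adjusted p = 0.349 with an estimated correlation). The scavenger receptor gene Cd163 was higher by 0.73 ± 0.16 (adjusted p = 0.0122), but was not called without wild-type 2 h replicate 3 or cub 2 h replicate 1 (adjusted p = 0.0924 and 0.0882, range over its alternatives 0.00557 to 0.0924). Of 12 mast cell markers, 8 were higher, or 10 adjusted over the list alone (median 0.48, camera adjusted p = 7.18e-10; adjusted p = 0.123 with an estimated correlation). Of 14 T cell markers, 1 was higher, or 1 higher and 1 lower adjusted over the list alone, with a median of −0.03, a mean of 0.01 and a downward test (camera adjusted p = 0.432). The alarmin gene Il33, which fibroblasts and keratinocytes express, was lower in cub (−0.61 ± 0.10, adjusted p = 0.00153).

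In total 880 genes differed at 2 h, 765 higher and 115 lower in cub. The split depended on the scaling of the arrays: 524 were higher and 269 lower after quantile normalization, and 591 and 177 after median-centring. Without wild-type replicates 2 and 3 the count was 514 and 402, and without cub replicate 1 it was 329.

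At 24 h, some cytokine genes were higher in cub. Il24, a cytokine of the interleukin 10 family, reached 9.09 ± 0.28 against 7.30 ± 0.10 (SD, n = 3 each), a difference of 1.79 ± 0.11 (adjusted p = 9.01e-09). Its relative Il19 was higher by 0.64 ± 0.10 (adjusted p = 0.00065), while Il20ra, a receptor chain for this cytokine family, was lower (−1.19 ± 0.13, adjusted p = 9.47e-06). Of 33 inflammatory cytokines and chemokines, 7 were higher and 0 lower by limma, and 16 adjusted over the list alone. The list stood above all other genes by camera (median 0.27, adjusted p = 4.42e-11), also with an estimated correlation (adjusted p = 0.0383). It passed in 12 of 12 other alternatives as well, with medians of 0.157 to 0.313. Those alternatives kept the preset correlation, so the stability of the call with an estimated one was not tested. Of 19 neutrophil markers, 5 were higher, or 6 adjusted over the list alone, among them the lectin Clec4e at 0.77 ± 0.14 (adjusted p = 0.00243). The camera call for neutrophil markers (adjusted p = 1.65e-08) did not hold with an estimated correlation (adjusted p = 0.132). Nor did that for 29 skeletal muscle genes (median 0.26, 4 higher, 8 adjusted over the list alone, camera adjusted p = 5.31e-07, medians of 0.163 to 0.343 over the alternatives; adjusted p = 0.376 with an estimated correlation). The same was true of 12 mast cell markers (median 0.24, 1 higher, also over the list alone, camera adjusted p = 0.000518, medians of 0.133 to 0.291; adjusted p = 0.317 with an estimated correlation). In all, 11 of 23 lists lay above other genes by camera and 2 below, and 1 of these calls held with an estimated correlation.

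Other genes higher in cub at 24 h were Arc by 1.62 ± 0.15 (adjusted p = 1.63e-06), the chitinase-like Chil3 of myeloid cells by 1.46 ± 0.14 (adjusted p = 1.63e-06), and the chromatin protein Hmga2, which is active in growing tissue, by 1.25 ± 0.11 (adjusted p = 1.1e-06). The kinin receptor gene Bdkrb1 was higher by 1.05 ± 0.09 (adjusted p = 1.1e-06), and the ErbB ligand gene Nrg1 by 0.61 ± 0.09 (adjusted p = 0.000335). Krt15, a keratin of basal and bulge cells, was lower (−1.08 ± 0.12, adjusted p = 1.7e-05), as were Mt4, a metallothionein of stratified epithelium (−1.1 ± 0.11, adjusted p = 1.89e-06), and Sostdc1, an inhibitor of BMP and Wnt signals (−1.03 ± 0.13, adjusted p = 6.91e-05). Of 18 sebaceous gland genes, 9 were lower, or 12 adjusted over the list alone, among them Cidea at −0.49 ± 0.09 (adjusted p = 0.00418). The camera call for sebaceous genes (median −0.27, adjusted p = 1.82e-08) was not held with an estimated correlation (adjusted p = 0.216). Of 24 cell division genes, 3 were lower, or 14 adjusted over the list alone, among them Aurka at −0.43 ± 0.07 (median −0.28, camera adjusted p = 2.2e-09; adjusted p = 0.3 with an estimated correlation). Of 21 fibroblast and matrix genes, 8 were higher, or 9 higher and 1 lower adjusted over the list alone (median 0.15, camera adjusted p = 1.82e-08; adjusted p = 0.282 with an estimated correlation).

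At 24 h 1133 genes differed, 447 higher and 686 lower in cub; median-centring made the split 599 higher and 556 lower. Without cub replicate 3 the count was 443.

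**Figure D2:**
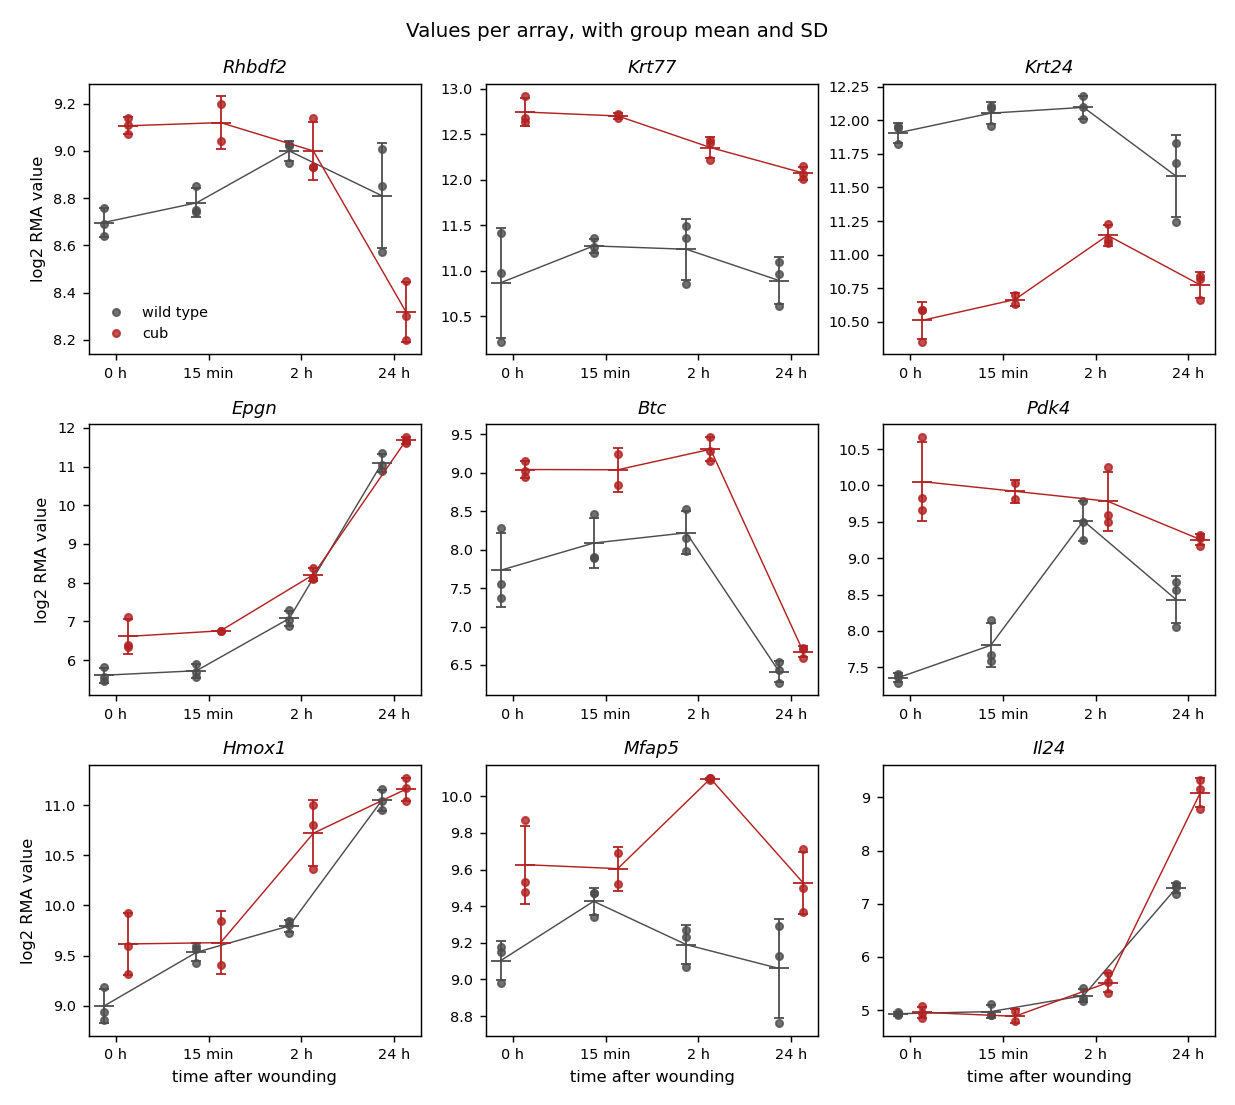
Log2 RMA values (y axis) of 9 genes by time after wounding (x axis) in wild type and cub, with 1 point per array, the group mean and the standard deviation. Pdk4 at 0 h lay at 10.05 in cub and 7.36 in wild type, and Il24 at 24 h at 9.09 and 7.30.

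Between genotypes 2299 genes were called at 1 time only. At 0 h, 15 min, 2 h and 24 h alike 35 genes were called, each with the same sign at all 4 times. The number depended on single arrays. At all times 6 genes were called without cub 15 min replicate 3, and 17 and 21 without cub 24 h replicates 1 and 3. There were 23 and 20 without wild-type 15 min replicates 2 and 3, and 22 without wild-type 24 h replicate 3. They included the keratins Krt77, Krt24 and Krt1, the EGFR ligand Epgn, the chemokines Ccl28 and Cxcl16, and the epidermal proteases Klk7 and Klk8. Averaged over the times, Krt77 was higher in cub by 1.40 ± 0.10 (adjusted p = 2.1e-08), Sectm1a by 1.1 ± 0.05 (adjusted p = 8.21e-12) and Epgn by 0.94 ± 0.08 (adjusted p = 3.23e-07). Btc was not among the 35 genes, though its average was higher by 0.90 ± 0.10 (adjusted p = 2.45e-06). At 24 h its arrays lay at 6.59 to 6.72 in cub and at 6.27 to 6.54 in wild type. Krt24 was lower (−1.14 ± 0.05, adjusted p = 2.28e-11), and Serpina3b and Lypd6 were lower by −1.46 ± 0.17 and −1.11 ± 0.08 (adjusted p = 6.8e-06 and 7.97e-09). Of 14 EGFR ligands, receptors and sheddases, 7 were higher and 0 lower by limma, also when adjusted over the list alone, with Ereg at 0.51 ± 0.11 and Tgfa at 0.30 ± 0.06 (camera adjusted p = 9.61e-05; adjusted p = 0.247 with an estimated correlation). The ligand gene Hbegf did not pass between genotypes at any time (0.13 ± 0.07 over all times, adjusted p = 0.23). Of 19 MAPK feedback targets, 8 were higher, or 11 adjusted over the list alone, among them Errfi1 at 0.19 ± 0.03 (adjusted p = 0.000222). This list passed by camera (adjusted p = 0.00236), but not with an estimated correlation (adjusted p = 0.287). EGFR signalling itself was not measured.

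The average over all times called 3641 genes, 1935 higher and 1706 lower, of which 13 differed at least 2-fold. The direction of the split was not stable: it was 1924 higher and 2208 lower after quantile normalization, and 1985 and 2058 with array weights. It also turned without cub 15 min replicate 2 (2007 and 2015) and without cub 2 h replicate 1 (1758 and 1859). Genes linked to a mutant allele travel with it when it is bred into another strain. Near Rhbdf2, differences were not shown to be more frequent than elsewhere: 16 of the 100 nearest tested genes (16%) against 3624 of 19818 others (18.3%), an odds ratio of 0.851 with a confidence interval of 0.465 to 1.47 (Fisher's exact p = 0.697, two-sided). With windows of 25 and 100 genes on each side, the odds ratios were 0.609 and 1.05 (Fisher's exact p = 0.358 and 0.783). The order of genes was taken from the GRCm38.p6 assembly.

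The antioxidant programme of NRF2, the pathway that the series title names, differed in single genes and in both directions. Hmox1, the haem oxygenase induced by NRF2 and by tissue injury, was higher in cub at 2 h, at 10.72 ± 0.33 against 9.80 ± 0.06 (SD, n = 3 each), a difference of 0.92 ± 0.15 (adjusted p = 0.001). The microsomal epoxide hydrolase Ephx1 was higher at 2 h by 0.33 ± 0.06 (adjusted p = 0.00312). The glutathione synthesis genes Gclc and Gclm were lower at 0 h, by −0.42 ± 0.08 (adjusted p = 0.00431) and −0.28 ± 0.06 (adjusted p = 0.00748). Averaged over the times, Hmox1 was higher by 0.44 ± 0.08 (adjusted p = 0.000437) and Nfe2l2, which encodes NRF2, by 0.13 ± 0.03 (adjusted p = 0.00472). The averages of Gclc and Gclm were −0.26 ± 0.04 (adjusted p = 0.000206) and −0.18 ± 0.03 (adjusted p = 0.000375). Nqo1 and Keap1 did not pass (−0.07 ± 0.06, adjusted p = 0.513, and −0.02 ± 0.03, adjusted p = 0.801).

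At 0 h, the cystine transporter Slc7a11 was lower in cub (−0.72 ± 0.15, adjusted p = 0.00669), a call that ended without wild-type 0 h replicate 2 or cub 0 h replicate 2 (adjusted p = 0.056 and 0.0543, range over its alternatives 0.00405 to 0.056). Hmox1 at 0 h (0.62 ± 0.15, adjusted p = 0.016) was not called without wild-type replicate 2 or 3 or cub replicate 2 (adjusted p = 0.0745, 0.0806 and 0.128, range 0.00661 to 0.128).

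Between genotypes, the 36 NRF2 targets as a set did not stand apart from other genes at 0 h (median −0.04, camera adjusted p = 0.213), 2 h (median 0.05, adjusted p = 0.105) or 24 h (median −0.03, adjusted p = 0.274). At 15 min the list lay below other genes (median −0.03, camera adjusted p = 0.0361), but not with an estimated correlation (adjusted p = 0.918) nor without cub 15 min replicate 3 (adjusted p = 0.183, range over the other alternatives 0.0197 to 0.534). Without wild-type 24 h replicate 3 the list passed at 24 h (adjusted p = 0.0386, range 0.0386 to 0.615). Over all times 5 members were higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.193). At 0 h 3 were higher and 5 lower, at 15 min 1 and 3, at 2 h 3 and 0, and at 24 h 0 and 2, against 4 and 5, 1 and 5, 6 and 1, and 0 and 2 adjusted over the list alone. In the comparison at 2 h, the direction of the list's median turned to −0.011 after quantile normalization. The wounding change of the list at 2 h was higher in cub (median 0.09, camera adjusted p = 0.00394, past the threshold in 17 of 18 other alternatives), but not with an estimated correlation (adjusted p = 0.321), and 0 members passed by limma, or 1 adjusted over the list alone.

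**Figure D3:**
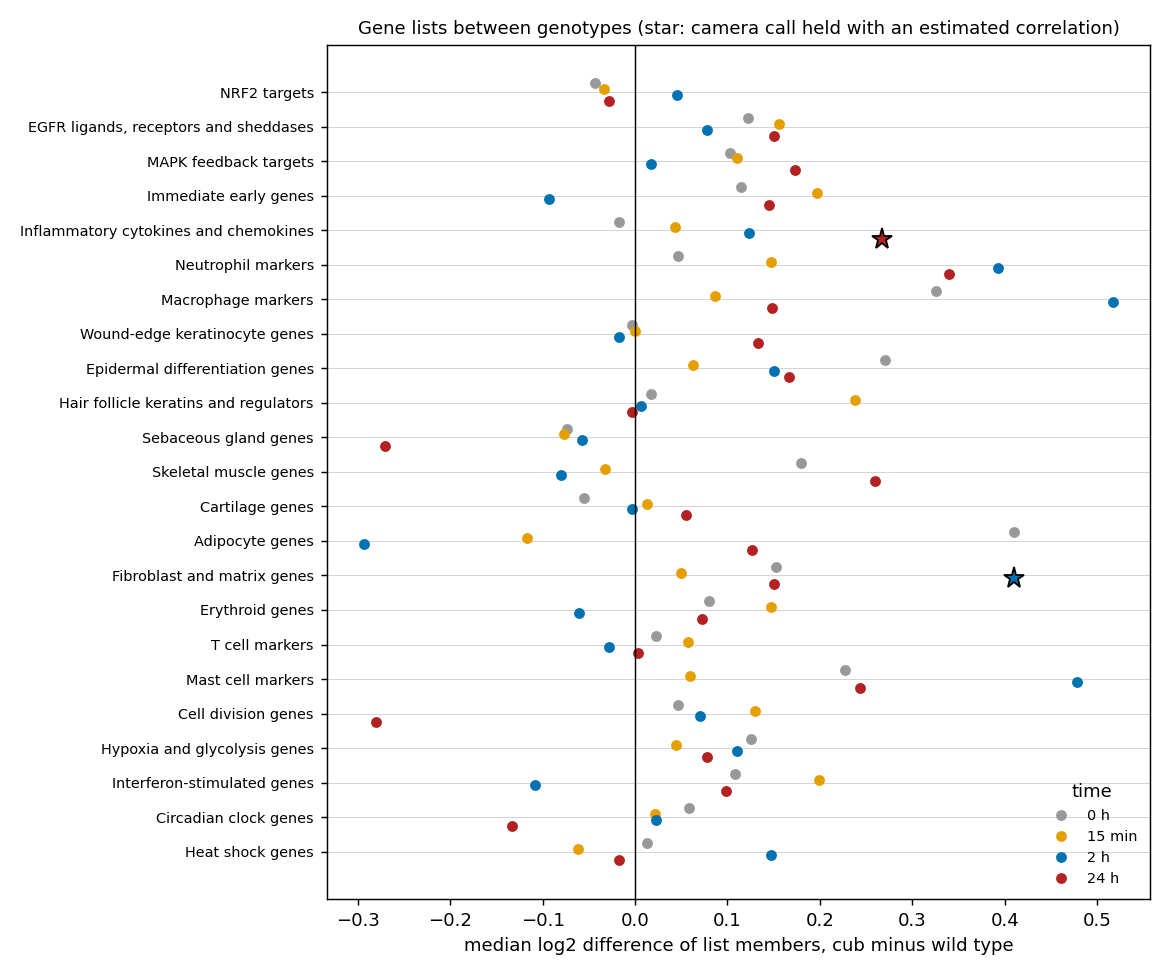
Median log2 difference between genotypes (x axis, cub minus wild type) of the 23 gene lists (y axis) at 0 h, 15 min, 2 h and 24 h, with a star where the camera call held with an estimated correlation. The stars mark fibroblast and matrix genes at 2 h, with a median of 0.41, and inflammatory cytokines and chemokines at 24 h, with a median of 0.27; the NRF2 median at 2 h turned to −0.011 after quantile normalization.

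Fos, the immediate early transcription factor gene, was the largest change 15 min after wounding in both genotypes. It rose by 1.66 ± 0.26 in wild type (adjusted p = 0.0205) and by 2.15 ± 0.29 in cub (adjusted p = 0.00583). Over the alternatives the adjusted p of Fos ran from 0.00189 to 0.183 in wild type and from 7.01e-06 to 0.537 in cub. In wild type, Zfp36, which speeds the decay of inflammatory messenger RNA, rose by 0.51 ± 0.09 (adjusted p = 0.0438), and Trex2, a nuclease of keratinocytes, by 0.63 ± 0.09 (adjusted p = 0.0125), with ranges of 0.00275 to 0.214 and 0.000372 to 0.183 over the alternatives. Of 28 immediate early genes, 2 rose in wild type, or 7 adjusted over the list alone (camera adjusted p = 1.05e-07; adjusted p = 0.419 with an estimated correlation), and 1 in cub, or 9 adjusted over the list alone (camera adjusted p = 1.81e-06; adjusted p = 0.572 with an estimated correlation).

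At 15 min, 7 genes were called in wild type, all higher, and 1826 had an unadjusted p under 0.05. The split was 5 and 1 after median-centring and 6 and 1 after quantile normalization. No gene was called without wild-type 15 min replicate 1 or 3 or without wild-type 0 h replicate 3, while 3 were called without 0 h replicate 2 and 13 without 0 h replicate 1. In cub 5 genes were called, 4 higher and 1 lower, or 2 and 1 after median-centring, and 2905 had an unadjusted p under 0.05. That count was 0 without cub 15 min replicate 3 or cub 0 h replicate 2, 12 without cub 0 h replicate 3, and 838 without cub 15 min replicate 2.

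By 2 h, wounding had induced cytokine and immediate early genes in both genotypes. Il6, a central cytokine of acute inflammation, rose by 4.51 ± 0.22 in wild type (adjusted p = 8.24e-12) and by 4.50 ± 0.22 in cub (adjusted p = 1.16e-11). The chemokine gene Ccl7 rose by 3.33 ± 0.14 and 3.68 ± 0.14, Il1b by 3.15 ± 0.24 and 3.99 ± 0.24, and the nuclear receptor gene Nr4a3 by 3.37 ± 0.16 and 3.29 ± 0.16. Tnfaip6, a hyaluronan-binding protein of inflamed tissue, rose by 3.52 ± 0.20 and 3.20 ± 0.20. The EGFR ligand genes Hbegf and Epgn rose in wild type by 2.12 ± 0.13 and 1.47 ± 0.16, and in cub by 2.27 ± 0.13 and 1.60 ± 0.16. Among NRF2-related genes, Hmox1 rose by 0.80 ± 0.15 in wild type and 1.1 ± 0.15 in cub, and Nfe2l2 by 0.43 ± 0.06 and 0.48 ± 0.06. Gclc and Gclm rose in cub, by 0.51 ± 0.08 (adjusted p = 0.000138) and 0.27 ± 0.06 (adjusted p = 0.00349), and in wild type did not pass (adjusted p = 0.17 and 0.751), but the difference between the genotypes did not pass either (adjusted p = 0.301 and 0.145).

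Of 28 immediate early genes, 27 rose in wild type and 25 in cub at 2 h, or 27 in each adjusted over the list alone. Of 33 inflammatory genes, 15 rose in wild type, and 17 rose and 1 fell in cub, or 17 and 18 rose and 1 fell in each adjusted over the list alone. Both camera calls held with an estimated correlation in both genotypes (adjusted p = 0.000516 and 0.00252 for immediate early genes, 0.00101 and 0.00252 for inflammatory genes). The MAPK feedback list held in wild type, where 9 of 19 rose, or 10 with 1 fallen adjusted over the list alone (camera adjusted p = 2.22e-09; adjusted p = 0.0182 with an estimated correlation). In cub 7 rose and 2 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.000593, and 0.192 with an estimated correlation). The difference between the genotypes in this list's wounding change passed by camera, but not with an estimated correlation. It also did not pass without cub 0 h replicate 1 (median −0.032, camera adjusted p = 0.0698). NRF2 targets in cub rose for 9 of 36 and fell for 0 by limma (camera adjusted p = 0.00136; adjusted p = 0.195 with an estimated correlation). In wild type 5 rose, and the list's median of −0.05 lay on the other side of 0 from its mean of 0.05 and from the direction of the test (adjusted p = 0.484).

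Wounding called 1590 genes in wild type at 2 h, 793 higher and 797 lower, of which 99 changed at least 2-fold, all higher. The nearly even split turned to 869 higher and 749 lower after median-centring, to 703 and 378 without wild-type 2 h replicate 2, and to 585 and 398, a count of 983, without wild-type 0 h replicate 2. Higher genes also outnumbered lower ones without any 1 of the other 4 arrays compared. In cub 2381 were called, 1528 higher and 853 lower, against 1406 and 1492 after quantile normalization, and 128 changed at least 2-fold, 123 higher and 5 lower. The changes of the genotypes, from separate arrays, had 591 higher and 261 lower genes in common and 7 of opposite sign, against 60.8 and 34.1 for independent lists (r = 0.713 across genes).

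At 24 h the wound edge carried keratinocyte activation, neutrophil and cytokine genes. Krt16 and Krt6b, keratins of migrating keratinocytes, rose in wild type by 6.10 ± 0.52 (adjusted p = 3.67e-09) and 5.77 ± 0.44 (adjusted p = 8.04e-10), and in cub by 6.30 ± 0.52 and 5.71 ± 0.44. Il1b rose by 5.90 ± 0.24 in wild type and 6.60 ± 0.24 in cub, the neutrophil chemokine gene Cxcl2 by 5.89 ± 0.25 and 6.41 ± 0.25, and the neutrophil calprotectin gene S100a8 by 5.60 ± 0.23 and 5.72 ± 0.23. Epgn rose by 5.48 ± 0.16 and 5.07 ± 0.16, whereas Btc dropped by 1.32 ± 0.19 in wild type and by 2.37 ± 0.19 in cub. The metallothionein gene Mt4 changed by −2.93 ± 0.11 and −3.51 ± 0.11, and Sema3d, a guidance cue, by −2.58 ± 0.12 and −2.97 ± 0.12. NRF2 targets moved both ways: Slc7a11 rose by 3.87 ± 0.15 and 4.93 ± 0.15, Gsta4 by 3.64 ± 0.09 and 3.93 ± 0.09, and Hmox1 by 2.05 ± 0.15 and 1.54 ± 0.15, while 12 of 36 members fell in each genotype. The numbers of NRF2 targets that rose were 16 in wild type and 18 in cub (camera adjusted p = 0.0931 and 0.142), or 17 and 20 adjusted over the list alone. Nqo1 rose by 0.74 ± 0.11 in wild type and 0.44 ± 0.11 in cub.

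Of 25 wound-edge keratinocyte genes, 24 rose in wild type and 25 in cub, also when adjusted over the list alone. Both camera calls held with an estimated correlation (adjusted p = 0.0038 and 0.00522). The same held for 19 neutrophil markers, of which 15 and 17 rose by either adjustment (adjusted p = 0.0146 in each genotype), and for 33 inflammatory genes, of which 29 and 30 rose, or 30 in each adjusted over the list alone (adjusted p = 0.00305 and 0.00224). The 14 EGFR ligands, receptors and sheddases moved both ways in wild type, with 5 higher and 7 lower, a median of −0.17, a mean of 0.53 and an upward test (adjusted p = 0.533). Wounding called 8543 genes in wild type, 4081 higher and 4462 lower, and 9177 in cub, 4208 higher and 4969 lower, or 4748 and 4551 after median-centring. Changes were at least 2-fold for 878 and 1164 genes. The genotypes had 3524 higher and 3894 lower genes in common and 6 of opposite sign, against 861 and 1110 for independent lists (r = 0.954 across genes, slope 1.06).

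By limma, the response to wounding differed between the genotypes for few genes at 2 h and more at 24 h. Splits of the genotypes within each time called as many genes in 10 of 100 cases at 2 h and in 6 of 100 at 24 h. All 9 and all 5 of the other splits that did so set the genotypes against each other between the 2 times. The shared genotype difference then entered the contrast, so these splits cannot decide. Chance stays open for both counts. At 24 h Il24 rose further in cub than in wild type, by 1.77 ± 0.16 (adjusted p = 7.32e-06), as did Arc by 1.73 ± 0.21 (adjusted p = 0.000305), Chil3 by 1.51 ± 0.19 (adjusted p = 0.000313) and Hmga2 by 1.28 ± 0.15 (adjusted p = 0.000305). Mmp3, which was lower in cub before wounding, had a more positive change in cub by 1.14 ± 0.17 (adjusted p = 0.00162). An interaction includes the difference at 0 h, so it need not mean a different level at 24 h. Pdk4 and Il12rb2, which were higher in cub before wounding, had a more negative change in cub at 24 h (−1.87 ± 0.32, adjusted p = 0.00514, and −1.38 ± 0.20, adjusted p = 0.00124). So had Mill1, a class I-like molecule of skin (−1.51 ± 0.19, adjusted p = 0.000313). The NRF2 target Slc7a11, which was lower in cub at 0 h, rose further in cub by 1.06 ± 0.21 (adjusted p = 0.0166). This call ended without cub 24 h replicate 3, wild-type 0 h replicate 2 or cub 0 h replicate 2 (adjusted p = 0.0533, 0.0582 and 0.0546, range over its alternatives 0.0138 to 0.0628). The change of Hmox1 was not shown to differ (−0.51 ± 0.21 at 24 h, adjusted p = 0.341; 0.30 ± 0.21 at 2 h, adjusted p = 0.671). Of 33 inflammatory genes, 3 rose further in cub, or 5 adjusted over the list alone (camera adjusted p = 9.12e-09; adjusted p = 0.0918 with an estimated correlation). At 2 h the change of Pdk4 was more negative in cub (−2.43 ± 0.32, adjusted p = 0.00359), a call that held in every left-out array but ended without empirical Bayes moderation (adjusted p = 0.0565, range over its alternatives 0.000503 to 0.0565).

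The interaction at 24 h called 200 genes, 51 with a more positive and 149 with a more negative change in cub, or 69 and 120 after median-centring. The count was 317 and 102 without cub 24 h replicates 2 and 3, 83 and 111 without wild-type 0 h replicates 2 and 3, and 118 and 90 without cub 0 h replicates 1 and 2. The interaction at 2 h called 26 genes, 21 more positive and 5 more negative, against 12 and 6 after median-centring and 21 and 16 after quantile normalization. It was 5, 2 and 4 without wild-type 2 h replicates 1, 2 and 3, and 2, 45 and 6 without cub 2 h replicates 1, 2 and 3. For 0 h arrays it was 1 and 4 without wild-type replicates 2 and 3, and 14, 1 and 10 without cub replicates 1, 2 and 3. The split turned to 2 more positive and 3 more negative without wild-type 2 h replicate 1, to 6 and 8 without cub 0 h replicate 1, and to 0 and 1 by limma without replicate 2 of either genotype at 0 h. At 15 min limma called 0 genes, with 1740 at an unadjusted p under 0.05; 1 gene was called without cub 0 h replicate 3.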

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

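Of the tests here, the 2 tests for dermis in the biopsies and the 2 tests made after subtracting the shared genotype difference were chosen only after the result was seen. The genes below stood out because their change on wounding differed between wild type and cub by a test of that difference itself. At 2 h, 26 genes did so and at 24 h 200 did.

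Single genes of several functions had a more positive change in cub at 2 h. Tyrp1 and Dct, which encode enzymes of melanin synthesis, differed by 1.35 ± 0.27 and 1.08 ± 0.17 (adjusted p = 0.0455 and 0.0226). The immediate early gene Arc differed by 1.24 ± 0.21 (adjusted p = 0.0268), the wound fibroblast gene Cthrc1 by 1.08 ± 0.17 (adjusted p = 0.0214), the adipokine gene C1qtnf3 by 0.86 ± 0.15 (adjusted p = 0.0268) and the microRNA gene Mir377 by 0.84 ± 0.15 (adjusted p = 0.029). A more negative change in cub was found for Pdk4 (−2.43 ± 0.32, adjusted p = 0.00359) and for Ucp3, a mitochondrial carrier of muscle (−1.23 ± 0.24, adjusted p = 0.039). The same direction held for Mill1 (−1.11 ± 0.19), the class I gene H2-Q5 (−0.73 ± 0.13) and Shisa7 (−0.50 ± 0.08), each at an adjusted p of 0.0268. All of these calls but that of Pdk4 ended without wild-type 0 h replicate 2, for example for Arc at an adjusted p of 0.0788 (range over its alternatives 0.000466 to 0.105), and without cub 0 h replicate 2.

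At 24 h the cytokine gene Il24 had the most positive difference (1.77 ± 0.16, adjusted p = 7.32e-06). It was followed by Arc at 1.73, Chil3 at 1.51, Hmga2 at 1.28, the pregnancy-specific glycoprotein gene Psg18 at 1.27 and Fgf23, a hormone of phosphate balance, at 1.27. The desaturase gene Scd3 had the most negative difference (−2.26 ± 0.50, adjusted p = 0.033), which was no longer called without wild-type 0 h replicate 2 (adjusted p = 0.1, range 0.00862 to 0.104). Pdk4 differed by −1.87, Mill1 by −1.51, Il12rb2 by −1.38 and Rhbdf2 by −0.90. The myosin gene Myh2 differed by −1.33 ± 0.27 (adjusted p = 0.0195) and Fcrls, a microglia and macrophage marker, by −1.20 ± 0.26 (adjusted p = 0.0302), and neither was called without wild-type 0 h replicate 2 (adjusted p = 0.0651, range 0.00502 to 0.0738, and 0.0787, range 0.0131 to 0.0939).

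Probe sets without a gene name were not used by the gene tests. Of 12146 such probe sets, 459 (3.78%) differed between genotypes over all times when every row was tested. The same test called 3995 of all 35556 rows, so unnamed probe sets were called less often than the rest.

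The excess of higher genes in cub at 2 h, 765 against 115, was weighed first. A larger share of dermis in the cub biopsies may account for part of it and stays open: the epidermal differentiation median was 0.15 in cub at 2 h, but 0.27 at 0 h, so its sign at 2 h decides nothing. The wounding change of that list was lower in cub (median −0.143, camera adjusted p = 0.000579) and that of fibroblast and matrix genes higher (median 0.253, adjusted p = 1.3e-09), the directions such a share would give, but neither passed with an estimated correlation (adjusted p = 0.397 and 0.321). Among abundant genes, Col1a1 was at 12.08 ± 0.13 in cub and 11.53 ± 0.11 in wild type and Krt10 at 13.16 ± 0.06 and 13.22 ± 0.02 (SD, n = 3 each). The epidermal genes Krt77, Krt1 and Ivl were higher in cub at 2 h, by 1.12, 0.76 and 0.46. At 0 h they were already higher, by 1.87, 1.14 and 0.70, so single genes decide nothing. Array scaling also stays open, since the lowest share of higher genes under the scaling alternatives was 66.1%, between the bounds set for it, as does an effect of the genotype, which was not tested apart.

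The second pattern was that most genes with a different change at 24 h, 149 of 200, had a more negative change in cub. A difference already present at 0 h may account for part of it: 40% of the 200 genes had a larger genotype difference at 0 h than at 24 h, 80 genes against 120, and that share decides for neither. Array scaling could account for part as well, since the lowest share of more negative genes under the scaling alternatives was 63.5%. The genotype remains an open and untested explanation.

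For the interactions, splits of the genotypes within each time called as many genes as the real split in 10 of 100 cases at 2 h, where the highest other split called 330 against 26, and in 6 of 100 at 24 h, where it called 519 against 200. Chance is not excluded by these splits. Splits that call several times the real count point to a structure of the samples, and all 9 and all 5 of the other splits that called as many set the genotypes against each other between the 2 times, so that the shared genotype difference entered the contrast. After this difference was subtracted, the real split alone, 1 of 100, called as many at each time, with 0 and 3 genes in the highest other split. The subtracted difference was fitted on the real labels and so took from the other splits what had made them call genes, so these values decide nothing and chance stays open.

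For the average over all times, chance alone is unlikely: 1 of 100 splits, the real one with 3641 genes, called as many, and the highest other called 4. That share is the smallest that 100 splits can give. The other splits, here and below, mixed the genotypes or times within groups, which adds their difference to the spread. Their counts are therefore not the number of calls to expect without a difference. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 1047 and 0 between genotypes at 0 h, 880 and 0 at 2 h, and 1133 and 43 at 24 h. For wounding they were 7 and 1 in wild type at 15 min, 1590 and 1 at 2 h and 8543 and 0 at 24 h, and in cub 2381 and 0 at 2 h and 9177 and 0 at 24 h.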

How the results depend on the processing

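The average over all times without the 15 min arrays was chosen only after the result was seen; it called 2849 genes, 1725 higher and 1124 lower, of which 2500 were also called with them. The number of arrays limits the precision of every value. With only the 13741 genes of a highest group mean of at least 6, no count moved by more than 1.5 times. Where 1 of the 2 cub arrays at 15 min was left out, the lone array was assumed to vary like the other groups. The cause of the changes below was not tested unless fewer genes or arrays are named.

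In cub at 15 min, wounding called 3 genes after median-centring. With every probe set tested, which adds tests, wounding at 15 min called 0 genes in wild type by limma and 16 in cub, and the interactions called 2 at 2 h and 120 at 24 h. With only the arrays of the groups compared, hence fewer arrays, the genotype comparisons called 514 at 0 h, 67 at 15 min and 258 at 24 h, wounding at 15 min called 26 in wild type and 0 in cub, and the interactions 10 and 74. Without empirical Bayes moderation, wounding at 15 min called 0 in wild type and 8 in cub, and the interactions 1 and 131. With trend and robust estimation, wounding at 15 min in wild type called 17. With array weights, the genotype comparisons called 1804, 218 and 1590 at 0 h, 15 min and 2 h. Wounding then called 389 and 2712 in wild type at 15 min and 2 h and 0 and 4112 in cub, and the interactions 173 and 437. With q values scaled by the share of true nulls, the genotypes differed in 1722 genes at 15 min and wounding in cub called 10. The NRF2 list at 15 min (median −0.033) was not past the threshold after quantile normalization (−0.004), with only genes of a highest mean of at least 6 (−0.033) or with an estimated correlation (−0.033).

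A pairing of the arrays by replicate number was not shown: in 0 of 8 comparisons with 3 pairs was every pair's correlation over 0.1, with values from −0.26 to 0.258. Such a rule cannot exclude a weak or partial pairing. In the 2 comparisons with 2 pairs, both at 15 min, the correlations were −0.296 and −0.191 between genotypes and 0.253 and 0.41 for wounding in cub, where both pairs were over 0.1. With the replicate number as a block, the genotypes differed in 414 genes at 15 min, wounding in cub at 15 min called 3 and the interaction at 2 h called 4.

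With each array left out in turn, the genotype counts ran from 322 to 957 at 0 h, 29 to 2025 at 15 min, 329 to 722 at 2 h, 443 to 1364 at 24 h and 2816 to 4022 over all times. For wounding they ran from 0 to 13, 983 to 1248 and 7796 to 8035 in wild type at 15 min, 2 h and 24 h, and 0 to 838, 1716 to 2007 and 8517 to 8717 in cub. For the interactions they ran from 0 to 1, 1 to 45 and 83 to 317. The NRF2 median ran from −0.065 to −0.023 at 0 h, −0.092 to −0.015 at 15 min, 0.009 to 0.077 at 2 h and −0.041 to −0.003 at 24 h.

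In all, the camera test of 4 list results turned in direction while it passed in 1 of the 2 fits. Skeletal muscle genes in wild type at 2 h went from −0.017 with an upward test to −0.098 with a downward one under array weights (−0.082 to 0.122 with an array left out). In wild type at 15 min the median went from 0.113 to 0.012 without wild-type 15 min replicate 1 and stayed positive, while the test turned downward without passing (adjusted p = 0.949; medians 0.002 to 0.198). Without cub 15 min replicate 3, fibroblast and matrix genes between genotypes at 15 min went from 0.05 to −0.043 (−0.043 to 0.133), and cartilage genes in the interaction at 15 min from 0.083 to −0.092 (−0.092 to 0.278).

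Of 781 calls of named genes, 540 held under every alternative. Sign changes that passed in neither fit occurred in 1 of 51 NRF2 list values, 256 of 4848 other list values and 37 of 18569 named gene values. An estimated correlation ended the NRF2 call between genotypes at 15 min and left the other 3 NRF2 results between genotypes at single times on their side of the threshold. Of all 149 list calls, it ended 136 and 13 held.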

Other observations

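Genes of deeper ear tissues were lower at 24 h than in unwounded ears in both genotypes. Wounded samples were rings of wound edge, and the size of the 0 h samples was not recorded here. A smaller share of these tissues in the samples therefore cannot be told apart from a fall in expression. The muscle gene Tcap, which encodes a protein that anchors titin in the sarcomere, changed by −1.13 ± 0.13 in wild type and −1.16 ± 0.13 in cub (adjusted p = 2.13e-07 and 1.2e-07). Of 29 skeletal muscle genes, 25 fell in wild type and 26 in cub, or 27 in each adjusted over the list alone (camera adjusted p = 2.09e-08 and 1.48e-07; adjusted p = 0.353 and 0.399 with an estimated correlation). The cartilage genes Ucma and Cnmd changed by −1.40 ± 0.16 and −1.33 ± 0.14 in wild type, where 15 of 20 cartilage genes fell, or 15 with 1 higher adjusted over the list alone (camera adjusted p = 7.89e-05; adjusted p = 0.33 with an estimated correlation). In cub 12 fell and 1 rose, also over the list alone (camera adjusted p = 0.00321; adjusted p = 0.412 with an estimated correlation). Of 13 adipocyte genes, 12 fell in wild type, among them Lpl, the lipase that feeds fat cells, at −1.23 ± 0.15 (camera adjusted p = 0.00049; adjusted p = 0.412 with an estimated correlation). In cub 13 of 13 fell (camera adjusted p = 0.000139; adjusted p = 0.399 with an estimated correlation). Between genotypes, adipocyte genes had medians of 0.41 at 0 h and −0.29 at 2 h, with no member past the threshold (camera adjusted p = 0.000141 and 0.000255; adjusted p = 0.551 and 0.512 with an estimated correlation). The 0 h call ended without cub 0 h replicate 2, which stood apart in these genes (median 0.06, adjusted p = 0.155, range over the alternatives 6.86e-10 to 0.208).

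Interferon-stimulated genes rose at 24 h in both genotypes. Rtp4 rose by 2.97 ± 0.21 in wild type and 2.37 ± 0.21 in cub, and the chemokine gene Cxcl10 by 2.58 ± 0.22 and 3.04 ± 0.22. Of 18 such genes, 17 rose in wild type and 18 in cub (camera adjusted p = 1e-11 and 2.31e-09; adjusted p = 0.0923 and 0.17 with an estimated correlation). Of 20 hypoxia and glycolysis genes, 12 rose and 2 fell in wild type (camera adjusted p = 0.00134; adjusted p = 0.397 with an estimated correlation), and over all times Egln3, an oxygen sensor, was higher in cub by 0.43 ± 0.08 (adjusted p = 0.00051). Of 13 heat shock genes, 10 rose and 2 fell in wild type (camera adjusted p = 0.000622; adjusted p = 0.212 with an estimated correlation), and Hspa1a was lower in cub at 24 h (−0.53 ± 0.08, adjusted p = 0.000417). Of 14 T cell markers, 1 rose and 4 fell in wild type at 24 h (camera adjusted p = 0.533), and of 9 erythroid genes 3 fell (camera adjusted p = 0.21).

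Circadian clock genes differed between the genotypes in both directions. Arntl, which encodes the activator BMAL1, was lower in cub over all times (−0.37 ± 0.04, adjusted p = 1.87e-06), as was Hlf (−0.43 ± 0.06, adjusted p = 5.39e-05), whereas Per1, a repressor of the clock, was higher by 0.36 ± 0.05 (adjusted p = 5.67e-05) and Dbp by 0.30 ± 0.04 (adjusted p = 2.56e-05). Of 16 clock genes, 5 were higher and 4 lower, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.987). Sampling of cub mice later in the day than wild type is a candidate explanation. It was tested by comparing the change of the 16 genes from 0 h to 2 h in wild type with their mean genotype difference at 15 min and 24 h, which gave a Spearman rho of 0.224 (permutation p = 0.402). The change in wild type sets wounded against unwounded tissue, so it mixes wounding with time of day and the test cannot decide. The explanation stays open, and an effect of the genotype was not tested apart from it.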
